A study of Mus musculus with 143 samples.

How the data were processed

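Tumours came from 11 mouse lines implanted under the skin of the lower flank. Per the labels' protocols, mice received muDX400 or the isotype antibody on days 11 and 15 after implantation and tumours were excised on day 19, which the labels call 8 days, and frozen. Per the same protocols, RNA was extracted with a phenol reagent, depleted of ribosomal RNA, made into stranded total RNA libraries and sequenced as 50 base paired-end reads on a HiSeq 4000. The table of the whole series holds FPKM values, fragments per kilobase of transcript scaled by the number of mapped fragments, as deposited by the authors, for 54232 gene identifiers, of which 54079 have a symbol, in 143 libraries. The aligner, the quantifier, the genome build, the annotation and any scaling between libraries are not given in the sources used here. Very small values between the steps of single fragments show that fragments shared between genes were divided by estimation, so pseudogenes and members of gene families are uncertain. All columns were matched to samples through the sample numbers in the descriptions, and 0 columns went unused.

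Depth was estimated per library from the commonest smallest step of the values of genes with a single annotated transcript. It was 36.7 to 50.4 M fragments in the 9 baseline libraries of B16F10, RENCA and TC1 and 11.6 to 25.9 M in the other 134. FPKM totals ran from 446984 to 885333 per library, and mitochondrial transcripts took 1.64% to 14.1% of them, with a median of 4.09%. The variance between the closest of 253 replicate pairs was 3.82 times that of counting noise and the median was 18.0 times, so no library was treated as a copy of another. The highest correlation within a pair was 0.997. Sample numbers fall in blocks. The baseline libraries of 8 models form one, the 8-day libraries of TC1, EMT6, LL2 and MC38 another, those of CM3, MBT2, MB49, CT26 and 4T1 another, and B16F10 and RENCA in all arms with the TC1 baseline the last. Both 8-day arms of a model always share a block.

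Values were analysed as log2(FPKM + 1), and every log2 difference is on that scale, which understates the change of low genes. Because FPKM are not counts, genes were tested with limma 3.58.1 in R 4.3.3 with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The designs, tests, lists and alternatives were fixed before the data were examined, except where stated. Exploratory fits were run while the scripts were being written, and the simulation test was completed after the first of them. Within each model 5 muDX400 and 5 isotype libraries were compared, on genes with an FPKM of at least 1 in at least 5 libraries. Class means were contrasts in a fit of all 110 libraries at 8 days, with a spread per gene shared over all models. For trends with response class, scored 0 for Resistant, 1 for Partial and 2 for High, the model was the replicate. The test used the 11 within-model effects, or the 11 model means of baseline or isotype libraries for genes with a mean FPKM of at least 1 in at least 3 models. Baseline and isotype libraries were compared as the mean difference over the 11 models in a fit of 33 and 55 libraries.

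The signature score was the mean over 18 genes, mouse counterparts of a published human signature, and was tested by exact 2-sided permutation within models (252 arrangements) and over the arrangements of classes over models (11550). Lists were tested within models with limma's fry, adjusted over all lists and models with at least 3 measured members, and across classes by exact permutation of the mean over members. The fry p tests whether the genes of a list move, on balance, one way and compares it with no other genes. Camera with a preset correlation of 0.01 and with an estimated correlation served as alternatives. It compares the genes of a list with the other genes tested, so its p and that of fry answer different questions. The 29 lists were T-cell-inflamed signature, pan T cell, CD8 T cell and cytotoxicity, CD4 and regulatory T cell, checkpoint and exhaustion, interferon-gamma response, type I interferon response, MHC class I and class II presentation, NK cell, B and plasma cell, dendritic cell, macrophage and monocyte, neutrophil, fibroblast and matrix, endothelial cell, proliferation, hypoxia and glycolysis, TGF-beta response, Wnt/beta-catenin, melanocyte lineage, epithelial, keratinocyte and skin, skeletal muscle, adipocyte, mast cell, erythroid, early stress genes and mitochondrial transcripts. Some genes stand in more than a single list, such as Tigit and Ciita.

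Genes were named by a fixed rule. Pdcd1, Cd274 and Cd8a were given in every comparison. Each model contributed its 4 largest rises and 4 largest falls among passing genes whose arms did not overlap, or all passing genes where there were 5 or fewer. Class means contributed the 12 largest rises and 8 largest falls with the same sign in every model of the class. Class trends contributed the 10 largest slopes in each direction, or the 10 smallest p where fewer than 5 genes passed. Baseline to isotype contributed the 10 largest rises and falls with the same sign in at least 9 of 11 models. Each list contributed up to 4 members with the smallest p, and the melanocyte list was given in every model. Predicted genes without a standard name, single immunoglobulin and T-cell receptor segments and ribosomal and small RNA genes count in totals only, Bc1 being kept by its standard name. Cd276, Fscn1 and Mmp9 were named after their values were seen, as members moving against their list. Some genes selected by this rule are not reported here.

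Gene names, positions, lengths (union of exonic bases) and GC content were taken from the GENCODE M21 mouse annotation on GRCm38 by gene identifier. Simulated data with known changes in genes drawn at random, built on the real means and spreads, were passed through the same fits. The simulated noise was normal and independent between genes and libraries. Changes of 1 and 2 log2 units were recovered for 87% and 100% of genes in MC38, 93% and 100% in MBT2, 91% and 99% in CT26, 96% and 100% in TC1, 58% and 93% in RENCA and 65% and 90% in CM3. A class slope of the effect of 0.5 or 1 was recovered for 79% and 97%.

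The alternatives chosen in advance were a pseudocount of 0.1, no filter, median-ratio scaling, quantile normalisation, the replicate number as a block, a spread shared over all 8-day libraries, a minimum change of 1 log2 unit, leaving out each library, replicate or model, High against Resistant models only, the mouse as replicate, the sample-number block as a term, model as a correlated block, a restriction to models sharing a block, and z-scores for the signature. Chosen after seeing the data were leaving out CM3 isotype replicates 2 and 3, or 2, 3 and 4, leaving out RENCA isotype replicate 2, restricting the time comparison to the 8 models of the first baseline block, list tests without each library, list means under each scaling and without each model, and removal of each library's GC and length trends. As many as 100 random splits of the samples, drawn with a fixed seed, were refitted for every result across genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.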

Results

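Gene expression was measured by total RNA sequencing in 143 subcutaneous tumours from 11 syngeneic mouse models, in which a mouse tumour cell line grows in an immunocompetent host. Each model contributed 3 untreated baseline tumours, 5 tumours collected 8 days after the first of 2 injections of a mouse IgG1 isotype control, and 5 tumours collected at the same time after muDX400, a mouse antibody against the inhibitory T-cell receptor PD-1. The labels place CM3, MBT2 and MC38 in the High response class, CT26, EMT6, MB49 and RENCA in the Partial class, and 4T1, B16F10, LL2 and TC1 in the Resistant class. The growth protocol describes a single injection site per mouse, so each library was taken to be the tumour of a separate mouse. Depth, estimated from the smallest steps between low values, was 21.1 M fragments in the median library. It ranged from 11.6 M (B16F10 muDX400 replicate 3) to 50.4 M. Between 10992 and 13328 genes per library had an FPKM of at least 1, with a median of 12508. Every one of the 143 libraries correlated best with another library of its own model.

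The melanocyte lineage list, which holds pigment enzymes and their regulators, served as a check of the labels. In isotype tumours its mean log2(FPKM + 1) was 8.65 in B16F10, a melanoma line, and 7.80 in CM3. The other 9 models lay between 0.22 and 0.54. Pdcd1 encodes PD-1, the target of the antibody. It lies on chromosome 1 at 94038305 to 94052553 of GRCm38 on the minus strand (ENSMUSG00000026285). Cd274 encodes its ligand PD-L1 and lies on chromosome 19 at 29367455 to 29388095 on the plus strand (ENSMUSG00000016496). Cd8a, which encodes a coreceptor of cytotoxic T cells, lies on chromosome 6 at 71373427 to 71379173 on the plus strand (ENSMUSG00000053977). All of them are annotated as protein coding.

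The first question was how far muDX400 altered the T-cell-inflamed signature, a set of 18 genes for antigen presentation, chemokines and cytotoxic lymphocytes, within each model. The score, a mean log2(FPKM + 1) over the genes, was 4.08 ± 0.32 in MC38 isotype tumours and 5.96 ± 0.40 after muDX400 (SD, n = 5 each), a difference of 1.88. In MBT2 it was 4.39 ± 0.28 and 5.39 ± 0.56, and in CM3 4.25 ± 0.73 and 5.25 ± 0.11. CT26 differed by 0.83, RENCA by 0.60 and EMT6 by 0.52. The remaining differences were 0.29 in LL2, 0.28 in B16F10, 0.22 in 4T1, 0.22 in MB49 and 0.09 in TC1. All 11 models had the higher mean after muDX400. The exact 2-sided permutation test over the 252 arrangements gave p = 0.00794 in MC38, the smallest p it can reach, 0.0159 in CT26, 0.0238 in MBT2 and 0.0476 in CM3. The exact p was 0.0556 in RENCA and in MB49, 0.0873 in 4T1, 0.0952 in LL2, 0.349 in EMT6, 0.476 in TC1 and 0.563 in B16F10. No model passed after Benjamini-Hochberg adjustment over the 11 models, where the lowest adjusted p of the exact test was 0.0873. A single model at the smallest reachable p, as MC38 was, could pass this adjustment only if other models had similarly small p. With 1 library left out, the adjusted exact p fell to 0.0437 in 4T1 without isotype replicate 3 (difference 0.30), CM3 without isotype replicate 4 (1.31), CT26 without muDX400 replicate 2 (0.95), MB49 without isotype replicate 2 (0.31) and MBT2 without muDX400 replicate 3 (1.21). In each of these fits the arms of the model no longer overlapped, so that model joined MC38 at the smallest reachable p. Median-ratio scaling gave the same adjusted exact p in CT26 (0.85) and MC38 (1.94).

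**Figure D1:**
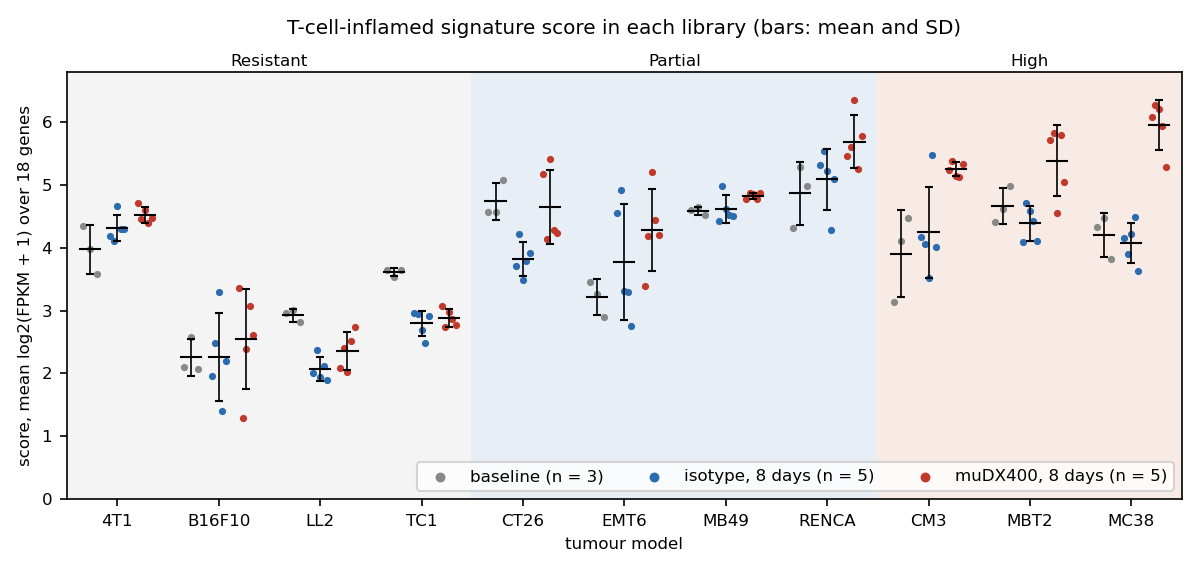
T-cell-inflamed signature score, the mean log2(FPKM + 1) over 18 genes, for each library (points) by tumour model and arm, with the group mean and SD (bars). MC38 isotype tumours averaged 4.08 and muDX400 tumours 5.96, while TC1 averaged 2.80 and 2.89.

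MC38, a colon carcinoma line, had the most genes past the threshold. Cd8a averaged 3.19 ± 1.31 FPKM in isotype tumours and 27.9 ± 11.1 after muDX400 (SD, n = 5 each), a rise of 2.72 ± 0.32 on the log2(FPKM + 1) scale (SE). Pdcd1 rose by 2.17 ± 0.30, from 2.23 ± 0.908 to 14.2 ± 5.68 FPKM, and Cd274 by 2.05 ± 0.25, from 11.8 ± 5.32 to 50.1 ± 11.8 FPKM. The largest rises among genes whose arms did not overlap were Cxcr6 (2.91 ± 0.34), a chemokine receptor of resident T cells, and Pdcd1lg2 (2.82 ± 0.24), which encodes the second PD-1 ligand. They were followed by Il18bp (2.79 ± 0.27), a decoy for interleukin 18, and Prf1 (2.77 ± 0.26), the perforin gene. Among the largest falls were Cxcl1 (−1.77 ± 0.19), a neutrophil chemokine, Hhip (−1.49 ± 0.21), an inhibitor of hedgehog signalling, and the sterol synthesis gene Msmo1 (−1.30 ± 0.20). Of 12775 genes tested with limma, 3482 passed, 1864 higher and 1618 lower. The adjusted p was 0.00113 for Pdcd1 and 0.00093 for Cd274 and Cd8a. The count was 1884 without muDX400 replicate 2, 1769 without muDX400 replicate 3, 2261 without muDX400 replicate 4, 2054 without isotype replicate 1 and 2290 without isotype replicate 5. The split into higher and lower was 2042 and 1077 without the expression filter, 1995 and 1008 after median-ratio scaling, and 2099 and 2915 after removal of GC and length trends.

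By gene list, lymphocyte and interferon genes of MC38 rose together. The CD8 T cell and cytotoxicity list rose by a mean of 2.06 log2 units with 13 of 14 measured members higher (13 adjusted over the list alone). Among them were Gzmb (2.77 ± 0.29) and Ifng (2.02 ± 0.23). The signature list had 16 of 18 members higher, with 16 higher and 1 lower adjusted over the list alone, and a mean of 1.88. In the pan T cell list 12 of 12 rose (mean 1.78) and in the CD4 and regulatory T cell list 6 of 7 (mean 1.16). Checkpoint and exhaustion genes rose in 9 of 10 (mean 1.70). Each of these had the same number adjusted over the list alone. Interferon-gamma response genes rose in 22 of 24 cases (24 adjusted over the list alone, mean 1.46), with Gbp2b at 2.70 ± 0.33. Type I interferon response genes rose in 13 of 16 (16 adjusted over the list alone, mean 0.74), MHC class II presentation genes in 10 of 10 (10, mean 1.35), and MHC class I presentation genes in 6 of 12 (9, mean 0.58). Limma's fry gave adjusted p = 0.00361 for the signature, CD8, CD4, checkpoint and interferon-gamma lists and 0.00523 for the pan T cell list. It was 0.00545 for MHC class II, 0.0252 for type I interferon and 0.0289 for MHC class I. With an estimated correlation between genes, limma's camera gave adjusted p = 0.393 for these lists and 0.449 for MHC class I, which was also lost when muDX400 replicate 1 was left out.

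Other cell types and pathways moved in MC38 as well. Macrophage and monocyte genes rose in 12 of 15 (13 adjusted over the list alone, mean 1.27), with Cd68 at 1.37 ± 0.19 and Ms4a7 at 1.64 ± 0.24. Mast cell genes rose in 5 of 6 (5, mean 1.57), endothelial genes in 9 of 10 (9, mean 0.92; Pecam1 1.45 ± 0.23), and NK cell genes in 2 of 4 (2, mean 0.63). Dendritic cell genes had 6 members higher and 1 lower of 9 (mean 0.60), with Xcr1 at 1.17 ± 0.17 and Fscn1 at −0.45 ± 0.13. Proliferation genes fell in 8 of 15 (10 adjusted over the list alone, mean −0.37; Top2a −0.41 ± 0.10), and hypoxia and glycolysis genes in 6 of 12 (7, mean −0.45; Slc2a1 −0.77 ± 0.16). The adipocyte list had a mean of 2.19 and did not pass (adjusted p = 0.0765 in limma's fry). Adjusted p in limma's fry was 0.00361 for the NK cell list, 0.00523 for proliferation and 0.00868 for macrophages. It was 0.0118 for dendritic cells, 0.0217 for mast cells, 0.0287 for hypoxia and 0.0377 for endothelium. With an estimated correlation, camera gave adjusted p = 0.451 for hypoxia and endothelium and 0.393 for the others. The endothelial call held only without muDX400 replicate 5 among the 10 left-out libraries. The hypoxia call was lost without muDX400 replicate 1 or 3 or isotype replicate 1. The 14 lists higher and 2 lower became 12 and 1 without muDX400 replicate 1 and 17 and 2 without muDX400 replicate 5.

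MBT2, a bladder carcinoma line, gave no single gene past the threshold but 9 lists. Cd274 averaged 12.3 ± 1.73 FPKM in isotype tumours and 54.4 ± 32.5 after muDX400 (SD, n = 5 each), a difference of 1.81 ± 0.40 log2 units (adjusted p = 0.0510). Pdcd1 differed by 1.12 ± 0.31 (0.0611) and Cd8a by 0.84 ± 0.33 (0.128). MHC class II presentation rose by a mean of 1.27 (Ciita, its transactivator, 1.60 ± 0.30), interferon-gamma response by 1.12 (Cxcl9 1.89 ± 0.40) and the signature by 1.00. The rise was 0.92 for checkpoint and exhaustion, 0.83 for CD4 and regulatory T cell, 0.64 for CD8 T cell and cytotoxicity (Prf1 0.77 ± 0.14) and 0.48 for MHC class I. Proliferation fell by a mean of 0.42 (Birc5 −0.52 ± 0.11) and the mitochondrial transcript list by 0.19 (mt-Nd4 −0.32 ± 0.06). The members higher when adjusted over the list alone were 10 of 10 for MHC class II, 24 of 24 for interferon-gamma, 15 of 18 for the signature and 12 of 13 for checkpoint. They were 5 of 5 for CD4, 12 of 14 for CD8 and 11 of 12 for MHC class I. On the same footing 15 of 15 proliferation and 4 of 9 mitochondrial genes were lower. Limma's fry gave adjusted p from 0.0241 for CD8 to 0.0426 for the signature. In camera with an estimated correlation, which compares a list with other genes, each of the 9 lists had adjusted p = 0.393.

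In limma 0 of 12541 MBT2 genes passed, with 3597 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0510. The gene count rose to 2595 without muDX400 replicate 3, 478 without muDX400 replicate 5 and 1 without isotype replicate 3, and to 816 after removal of GC and length trends. The list calls, 7 higher and 2 lower, became 4 and 0 without muDX400 replicate 1, 2 and 0 without muDX400 replicate 2, 9 and 2 without muDX400 replicate 3, 2 and 0 without muDX400 replicate 4, and 7 and 1 without muDX400 replicate 5. They became 1 and 0 without isotype replicate 1, 10 and 1 without isotype replicate 2, 3 and 0 without isotype replicate 3, 3 and 1 without isotype replicate 4, and 1 and 0 without isotype replicate 5. Among them the CD8 list of MBT2 held in each of the 10 fits.

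CM3 carried the higher T-cell transcripts in most but not all comparisons of single tumours. Pdcd1 averaged 2.63 ± 1.94 FPKM in isotype and 7.75 ± 0.665 in muDX400 tumours (SD, n = 5 each), a difference of 1.41 ± 0.28 log2 units. Cd274 averaged 52.6 ± 51.2 and 123 ± 9.38 FPKM (1.77 ± 0.58), and Cd8a 2.59 ± 2.41 and 7.12 ± 0.831 (1.42 ± 0.39), each with adjusted p = 0.179. The checkpoint and exhaustion list rose by a mean of 1.08 (9 of 10 higher adjusted over the list alone) and CD8 T cell and cytotoxicity by 0.97 (11 of 13). The neutrophil list rose by 0.80 (6 of 9) and the mast cell list by 0.78 (5 of 7; Cpa3 1.16 ± 0.28), with no member past the threshold over all genes. Adjusted over the list alone, macrophage genes of CM3 were higher in 11 of 15 (mean 1.01), endothelial in 7 of 11 (0.60), adipocyte in 7 of 9 (1.10) and fibroblast in 0 of 13 (0.97), and proliferation genes lower in 10 of 15 (−0.75). None of these 5 lists passed in limma's fry (adjusted p = 0.0597, 0.0613, 0.0816, 0.215 and 0.107). The Wnt/beta-catenin list rose on 3 measured members with a mean of 0.40 and a median of 0.09, led by Apcdd1 (1.07 ± 0.30), an inhibitor of that pathway. Limma's fry gave adjusted p = 0.0377 for CD8, Wnt and mast cell, 0.0409 for checkpoint and 0.0426 for neutrophil. Camera with an estimated correlation gave these lists, in the same order, adjusted p = 0.424, 0.617, 0.430, 0.430 and 0.430.

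Isotype replicates of CM3 stood apart. Replicate 4 had a signature score of 5.47 beside 3.52 to 4.17 in the other isotype tumours and 5.14 to 5.38 in muDX400 tumours. Replicates 2 and 3 correlated at 0.969 with each other and less with the rest. Limma passed 0 of 12945 CM3 genes, with 3441 at an unadjusted p under 0.05 and a lowest adjusted p of 0.102, against 3942 genes without isotype replicate 4. The 5 CM3 lists fell to 0 without muDX400 replicate 1, 2 or 5 or isotype replicate 1 or 5. They came to 1 without muDX400 replicate 3 or 4 or isotype replicate 3, to 2 without isotype replicate 2, and to 18 higher and 1 lower without isotype replicate 4. The median over all CM3 genes was 0.13 and shifted by −0.11 without the expression filter and by −0.14 after quantile normalisation.

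RENCA, a renal carcinoma line, showed another set of genes. The largest rises were Il11 (4.03 ± 0.59 log2 units, SE, n = 5 each), a cytokine of the interleukin 6 family, and Reg3g (3.16 ± 0.51), an antimicrobial lectin. Next came Saa3 (2.74 ± 0.24), an acute phase protein, and Il1rl1 (2.49 ± 0.41), the receptor of interleukin 33. Acp5 (−1.76 ± 0.39), Oscar (−1.74 ± 0.30) and Dcstamp (−1.39 ± 0.30), which mark osteoclasts and their fusion, fell with Cyp2s1 (−1.44 ± 0.33). Cd274 rose by 1.08 ± 0.22, from 19.6 ± 3.60 to 43.5 ± 12.1 FPKM (adjusted p = 0.0292), while Pdcd1 (0.62 ± 0.41, 0.549) and Cd8a (0.62 ± 0.43, 0.586) did not pass. RENCA isotype replicate 2 had a B and plasma cell score of 5.94 beside a group mean of 1.67, and without it the CD4 and regulatory T cell and dendritic cell lists also passed in fry. Neutrophil genes had 6 members higher and 1 lower of 11 (9 and 1 adjusted over the list alone, mean 1.08), with Csf3r at 1.69 ± 0.15, Il1b at 1.10 ± 0.18 and Mmp9 at −2.15 ± 0.45. Endothelial genes rose in 5 of 11 (10 adjusted over the list alone, mean 0.93; Emcn 1.44 ± 0.23) and checkpoint genes in 2 of 11 (4, mean 0.58; Entpd1 0.88 ± 0.16). Interferon-gamma response genes rose in 2 of 24 (12, mean 0.55; Gbp4 1.09 ± 0.24) and TGF-beta response genes in 2 of 10 (4, mean 0.35; Tagln 1.20 ± 0.19). The early stress list, a sign of handling as well as signalling, rose by a mean of 0.39 (0 of 10 past the threshold, 4 adjusted over the list alone). Proliferation fell by a mean of 0.45 (0 of 15, 6 adjusted over the list alone).

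Limma's fry gave adjusted p in RENCA of 0.00523 for endothelium, 0.0118 for neutrophil and 0.0155 for checkpoint. It was 0.0315 for stress, 0.0377 for interferon-gamma and TGF-beta and 0.0426 for proliferation. In camera with an estimated correlation the adjusted p was 0.289 for endothelium and checkpoint and 0.393 for the other lists. Of 12664 RENCA genes limma passed 325, 289 higher and 36 lower. After removal of GC and length trends 472 were higher and 132 lower, and with a spread shared over all 8-day libraries 2629 passed. The count was 95, 103, 758 and 100 without muDX400 replicates 1, 2, 3 and 4, 150 without isotype replicate 3, 100 without isotype replicate 5 and 127 without the expression filter. Over the 10 left-out libraries the interferon-gamma and stress calls held in 4 each and the TGF-beta and proliferation calls in 3 each, while endothelium, neutrophil and checkpoint held in 10.

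CT26, a colon carcinoma line, had 41 of 12094 genes past the threshold in limma, 35 higher and 6 lower. The largest rises were the matrix genes Mmp2 (1.24 ± 0.22 log2 units, SE, n = 5 each) and Eln (1.05 ± 0.19), with Pi16 (1.15 ± 0.20), a fibroblast marker, and Penk (1.12 ± 0.18), an opioid precursor. The largest falls were Tcim (−0.71 ± 0.12), Ndst3 (−0.68 ± 0.11), a heparan sulphate enzyme, Btc (−0.65 ± 0.10), a growth factor, and Dkk2 (−0.59 ± 0.09), a Wnt antagonist. Macrophage and monocyte genes rose in 4 of 15 (10 adjusted over the list alone, mean 0.40), with Cd68 from 71.5 ± 3.01 to 102 ± 4.83 FPKM (0.50 ± 0.05) and Trem2 at 0.45 ± 0.06. Other lists of CT26 had larger means and did not pass in limma's fry: adipocyte 1.14 (adjusted p = 0.0691), MHC class II 0.99 (0.0619), signature 0.83 (0.0691), interferon-gamma 0.82 (0.0896), pan T cell 0.75 (0.112) and mast cell 0.57 (0.102). Pdcd1 (1.07 ± 0.31, adjusted p = 0.138), Cd274 (0.71 ± 0.34, 0.273) and Cd8a (0.78 ± 0.38, 0.288) did not pass. The macrophage list had adjusted p = 0.00361 in limma's fry and adjusted p = 0.275 in camera with an estimated correlation. It held in each of the 10 fits with a library left out, with 3 lists passing without muDX400 replicate 2. Every left-out library moved the gene count of CT26: without muDX400 replicates 1 to 5 in turn it was 6, 8, 125, 6 and 17, and without isotype replicates 1 to 5 it was 5, 4, 5, 122 and 6. It was 21 higher and 0 lower without the expression filter, 94 after median-ratio scaling and 146 after quantile normalisation.

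TC1, a transformed lung epithelial line of the Resistant class, had 10 of 12470 genes higher and 0 lower in limma, with 817 at an unadjusted p under 0.05. They included Cxcl14 (2.12 ± 0.31 log2 units, SE, n = 5 each), a chemokine, Ccn5 (1.67 ± 0.23) and Mfap5 (1.10 ± 0.18), which encode matrix proteins, and the complement gene C2 (0.97 ± 0.14). Endothelial genes rose in 2 of 10 (10 adjusted over the list alone, mean 0.49), with Pecam1 from 12.3 ± 1.47 to 20.9 ± 3.62 FPKM (0.72 ± 0.11) and Cdh5 at 0.69 ± 0.11. TGF-beta response (0 of 10, 2 adjusted over the list alone, mean 0.22), mast cell (0 of 4, 4, mean 0.56) and neutrophil (1 of 6, 4, mean 0.50; S100a9 0.94 ± 0.14) rose as lists. Adipocyte (mean 1.14, adjusted p = 0.185 in limma's fry), erythroid (0.90, 0.219), epithelial (0.49, 0.0515) and mitochondrial transcripts (−0.17, 0.0603) did not pass, the last being lower past the threshold without muDX400 replicate 5. Cd274 differed by −0.04 ± 0.18 (adjusted p = 0.982), and Pdcd1 and Cd8a were below the expression filter. In limma's fry the adjusted p was 0.00523 for TGF-beta, 0.0155 for endothelium, 0.0217 for mast cell and 0.0315 for neutrophil. Camera with an estimated correlation gave these lists, in the same order, adjusted p = 0.275, 0.289, 0.275 and 0.339. The neutrophil call of TC1 was kept only without muDX400 replicate 4 or isotype replicate 2 or 5. The gene count was 0 without muDX400 replicate 2 or 5 or isotype replicate 1, 2, 3 or 4. It was 3 without muDX400 replicate 3, 36 without muDX400 replicate 1, 1 without the expression filter and 6 after quantile normalisation.

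In the other models limma passed no gene and fry no list. The counts at an unadjusted p under 0.05 were 601 of 12854 genes in 4T1, 351 of 11446 in B16F10, 538 of 12695 in EMT6, 1973 of 11904 in LL2 and 1247 of 12412 in MB49. Cd274 differed by 0.09 ± 0.19 in 4T1 (adjusted p = 0.982), 0.62 ± 0.36 in B16F10 (0.827), 1.02 ± 0.66 in EMT6 (0.907), −0.15 ± 0.11 in LL2 (0.435) and 0.13 ± 0.16 in MB49 (0.824). Pdcd1 differed by 0.32 ± 0.19 in 4T1 (0.970), 0.23 ± 0.34 in EMT6 (0.915) and 0.39 ± 0.22 in MB49 (0.566). Cd8a differed by 0.10 ± 0.18 (0.981), 0.26 ± 0.43 (0.922) and 0.36 ± 0.23 (0.626) in the same models. Both genes were below the expression filter in B16F10 and LL2. Mitochondrial transcripts in B16F10, a sign of RNA quality, had a mean difference of 1.20 (adjusted p = 0.177 in limma's fry). 4T1 gave the signature and MHC class I lists without isotype replicate 3, and B16F10 the proliferation list, lower, without isotype replicate 4. LL2 gave 101 genes without muDX400 replicate 1 and the macrophage list without isotype replicate 2. MB49 gave the interferon-gamma list without muDX400 replicate 2 and 3 lists (signature, pan T cell and interferon-gamma) without isotype replicate 2. Simulated changes of 1 log2 unit were recovered for 94% of genes in 4T1, 67% in B16F10, 91% in EMT6, 90% in LL2 and 87% in MB49, as against 87% in MC38 and 65% in CM3. Those changes were put in genes drawn at random, with independent noise. The shares therefore do not give the power for genes of larger spread, such as Cd274 in EMT6, or for samples with a shared structure. Over all models 42 of 267 pairs of model and list passed in fry, 37 higher and 5 lower, and 0 passed in camera with an estimated correlation. Camera with the preset correlation kept 36 of the 37 higher pairs, 14 of 14 in MC38, 7 of 7 in MBT2 and 4 of 5 in CM3. That setting passed 138 pairs in all, against 42 in fry, so this agreement is weak support.

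**Figure D2:**
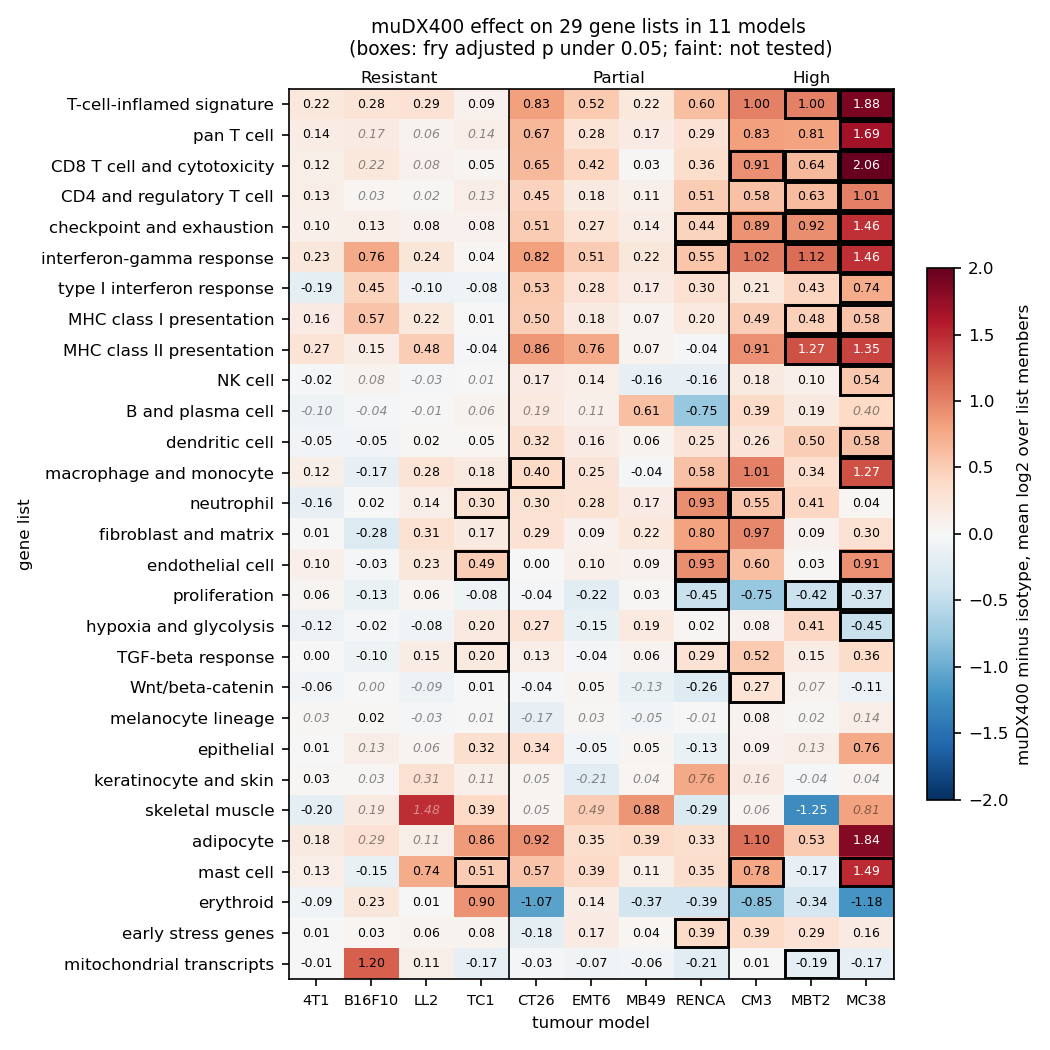
Mean muDX400 minus isotype difference in log2(FPKM + 1) over the members of 29 gene lists (vertical) in 11 tumour models (horizontal), with boxes around adjusted p under 0.05 in limma's fry and faint type for pairs not tested. Over the members passing the filter in all 8-day libraries, the signature ran from 0.09 in TC1 to 1.88 in MC38.

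The next comparison averaged the muDX400 effect over the models of each response class. Over the 3 High models Pdcd1 rose by 1.57 ± 0.18 log2 units (SE), Cd274 by 1.87 ± 0.23 and Cd8a by 1.66 ± 0.20, each higher in 3 of 3 models. The largest rises in the same direction in every High model were Mup22 (2.10 ± 0.45), a urinary protein, Acod1 (2.09 ± 0.24), the itaconate enzyme of activated macrophages, Il18bp (1.97 ± 0.25), and complement C3 (1.93 ± 0.26). They were followed by Gbp2b (1.85 ± 0.18), Cyp2e1 (1.84 ± 0.40), Pdcd1lg2 (1.83 ± 0.19), Serpina3f (1.82 ± 0.20), Gbp10 (1.80 ± 0.24), Calhm6 (1.73 ± 0.24) and Cxcr6 (1.72 ± 0.18). Among the largest falls were Pcdhgc4 (−1.04 ± 0.40), Hba-a1 (−0.99 ± 0.40), a globin, Dnph1 (−0.93 ± 0.13), Idi1 (−0.89 ± 0.19), Rpgrip1 (−0.87 ± 0.26), Fdps (−0.86 ± 0.11) and Gpx4-ps2 (−0.85 ± 0.16). Of these, Idi1 and Fdps act in sterol synthesis and Gpx4-ps2 is a pseudogene whose reads may be shared with its parent. Of 16187 genes, limma passed 6810 in the High class, 4000 higher and 2810 lower, with adjusted p = 8.26e-11 for Pdcd1, 5.24e-10 for Cd274 and 3.87e-10 for Cd8a. The error is between mice, so it covers these models and not models in general. Without CM3 the count was 4457, and the split was 3077 higher and 4288 lower after quantile normalisation and 3548 and 3926 after removal of GC and length trends. The fit shares a spread over all models, with which CM3 alone passed 6662 genes against 0 with its own. The error of models of larger spread may therefore be understated.

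T-cell, checkpoint, interferon-gamma and MHC class II lists rose nearly as a whole in the High class, and most other immune lists in part. Over all genes 4000 of 16187 were higher. B and plasma cell lay under that share and neutrophil not far above it. Counts are of members past the threshold over all genes, and unless stated the same number passed adjusted over the list alone. Pan T cell rose in 14 of 14 (Cd3g 1.66 ± 0.21), CD8 T cell and cytotoxicity in 13 of 14 (Prf1 1.65 ± 0.18) and CD4 and regulatory T cell in 10 of 10 (Icos 1.33 ± 0.14). Checkpoint and exhaustion rose in 13 of 13 (Ctla4 1.26 ± 0.14) and the signature in 16 of 18 (Tigit 1.39 ± 0.15) with Cd276 (−0.17 ± 0.07) lower. Interferon-gamma response rose in 22 of 24 (Nos2 1.67 ± 0.23; Ido1 1.27 ± 0.17) and type I interferon response in 11 of 16 (12 adjusted over the list alone; Ifit2 0.78 ± 0.17). MHC class I rose in 7 of 12 (8; Nlrc5 0.88 ± 0.16) and MHC class II in 10 of 10 (Ciita 1.69 ± 0.24). Macrophage and monocyte rose in 14 of 15 (Arg1 1.62 ± 0.25; Trem2 1.04 ± 0.17) and dendritic cell in 10 of 12 with Fscn1 (−0.36 ± 0.09) lower (11 and 1; Clec9a 0.93 ± 0.13). NK cell rose in 5 of 9 (Klre1 0.59 ± 0.10), B and plasma cell in 1 of 8 (Jchain 1.19 ± 0.42) and neutrophil in 5 of 14 (Csf3r 1.26 ± 0.15). Proliferation fell in 15 of 15 (Birc5 −0.84 ± 0.12; Cdk1 −0.57 ± 0.08). Without MC38 the members higher were 0 of 9 for NK cell, 4 of 16 for type I interferon and 10 of 15 for macrophage and monocyte. Without CM3 they were 2 of 14 for neutrophil and 4 of 12 for MHC class I, and B and plasma cell had 0 when any of the 3 models was left out. Neutrophil had 3 of 14 higher without MBT2.

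Stromal and other lists of the High class varied in the number of members past the threshold. Early stress, epithelial, melanocyte, hypoxia and Wnt lists had higher members near or under the share over all genes, 4000 of 16187. Endothelial genes rose in 10 of 11 (11 adjusted over the list alone; Pecam1 0.76 ± 0.12) and fibroblast and matrix in 6 of 13 (Lum 1.12 ± 0.26). TGF-beta response rose in 6 of 11 (Ltbp2 0.78 ± 0.14), mast cell in 6 of 7 (7; Cpa3 0.91 ± 0.19) and adipocyte in 9 of 9 (Plin1 1.56 ± 0.29; Lipe 1.00 ± 0.17). Early stress genes had 3 higher and 1 lower of 10 (Atf3 0.92 ± 0.16; Ier2 −0.26 ± 0.07) and epithelial 2 of 9 higher (1; Krt18 0.64 ± 0.25). Melanocyte had 2 of 9 higher (Tyrp1 0.28 ± 0.09, and 0.00 without CM3) and hypoxia and glycolysis 2 higher and 1 lower of 12 (1 and 1; Ldha −0.21 ± 0.08). Skeletal muscle (Myh1 −0.57 ± 0.22) and erythroid (Hba-a1) each had 1 member lower, of 10 and 5, and 0 adjusted over the list alone. Wnt/beta-catenin had 1 of 7 higher (Rnf43 0.25 ± 0.07), and keratinocyte and mitochondrial lists 0 of 6 and 0 of 9. The list mean changed sign under other scalings for Wnt (0.08 against −0.05 after quantile normalisation and −0.04 after trend removal) and keratinocyte (0.05 against −0.02 after quantile normalisation). It did so for mitochondrial (−0.12 against 0.03 and 0.12) and hypoxia genes (0.015 against −0.029 after trend removal). The muscle mean of −0.13 was 0.43 without MBT2. The hypoxia mean was −0.18 without MBT2 (1 higher, 4 lower) and 0.25 without MC38 (5 higher, 0 lower), as MC38 (−0.45) and MBT2 (0.41) went opposite ways. Without MC38 the members higher were 0 of 7 for mast cell (mean 0.31), 4 of 11 for endothelial, 3 of 11 for TGF-beta and 5 of 9 for adipocyte genes. Without CM3 they were 2 of 13 for fibroblast and matrix and 3 of 11 for TGF-beta, and the Wnt, keratinocyte and hypoxia means turned to −0.021, −0.0025 and −0.020. Epithelial had 0 of 9 higher without MC38, and Wnt 3 of 7 without MBT2.

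Over the 4 Partial models Pdcd1 rose by 0.58 ± 0.16 log2 units (SE; adjusted p = 0.0119) and Cd274 by 0.74 ± 0.20 (0.0123), and Cd8a stood at 0.51 ± 0.18 (0.0630). The largest rises in the same direction in every Partial model were Saa3 (1.76 ± 0.33), Sfrp2 (1.41 ± 0.26), Cxcl12 (1.31 ± 0.24), Mfap4 (1.24 ± 0.20) and Pi16 (1.20 ± 0.25). They were followed by Cpxm1 (1.18 ± 0.26), Ccl5 (1.16 ± 0.23), Sfrp1 (1.13 ± 0.17), Ly6i (1.08 ± 0.19), Itm2a (1.07 ± 0.17), H19 (1.02 ± 0.23) and Hp (1.00 ± 0.33). Several of these are made by fibroblasts, among them Sfrp2, Cxcl12, Mfap4 and Pi16, and Saa3 and Hp are acute phase genes. The largest falls were Gzmc (−0.76 ± 0.21), a granzyme, Cx3cr1 (−0.60 ± 0.13), a chemokine receptor, and Stra6 (−0.57 ± 0.16). Next were Pcdh18 (−0.50 ± 0.08), Fgf21 (−0.46 ± 0.15), Cp (−0.46 ± 0.11), Padi3 (−0.42 ± 0.12) and Npnt (−0.40 ± 0.10). Limma passed 1078 genes, 734 higher and 344 lower. The count was 708, 702 and 313 without replicates 3, 4 and 5 of every model, and 31 without RENCA. The split was 928 and 223 after median-ratio scaling and 897 and 654 after removal of GC and length trends. With the spread shared over all models, as in this fit, RENCA alone passed 2629 genes against 325 with its own. The error of the Partial mean may therefore be understated.

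By list, with the number adjusted over the list alone after each count, the Partial class had higher members for the signature in 7 of 18 (15; Ido1 0.67 ± 0.15) and CD4 and regulatory T cell in 7 of 10 (9; Foxp3 0.38 ± 0.08). Higher members were found for CD8 in 4 of 14 (10; Ifng 0.80 ± 0.16), pan T cell in 3 of 14 (9; Cd2 0.62 ± 0.17), checkpoint in 5 of 13 (9) and interferon-gamma response in 8 of 24 (18). Neutrophil had 9 higher and Mmp9 (−0.77 ± 0.19) lower of 14 (12 and 1; Cxcr2 0.63 ± 0.10; Clec4e 0.67 ± 0.14). Fibroblast and matrix had 4 of 13 higher (8; Col1a1 0.76 ± 0.22), endothelial 4 of 11 (10; Emcn 0.41 ± 0.10) and macrophage 3 of 15 (4; Arg1 0.73 ± 0.22). Dendritic cell had 2 of 12 (5), type I interferon 2 of 16 (11; Isg15 0.41 ± 0.13), TGF-beta 1 of 11 (Tagln 0.75 ± 0.14) and mast cell 1 of 7 (Hdc 0.62 ± 0.11). NK cell had Itga2 (−0.29 ± 0.08) lower of 9 and Wnt/beta-catenin had Apcdd1 (−0.37 ± 0.10) lower of 7. The MHC class I and II, B cell, proliferation, hypoxia, melanocyte, epithelial, keratinocyte, muscle, adipocyte, erythroid, stress and mitochondrial lists had 0 members past the threshold. Without RENCA every list had 0 members past the threshold, with list means of 0.52 against 0.54 for the signature and 0.064 against 0.28 for endothelial genes. Without CT26 the members higher were 4 of 18 for the signature, 0 of 14 for pan T cell, 2 of 14 for CD8 and 2 of 24 for interferon-gamma response. They were 0 of 15 for macrophage, 1 of 13 for fibroblast and matrix, 0 of 16 for type I interferon and 0 of 12 for dendritic cell.

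Over the 4 Resistant models Pdcd1 stood at 0.24 ± 0.16, Cd274 at 0.13 ± 0.20 and Cd8a at 0.16 ± 0.18 (SE, adjusted p = 1.00 each). Limma passed 0 of 16187 genes, with 441 at an unadjusted p under 0.05, and 0 members of each of the 29 lists. Adjusted over the list alone, 5 of 11 endothelial, 4 of 7 mast cell and 7 of 9 mitochondrial genes were higher, with list means of 0.20, 0.31 and 0.28. The mitochondrial mean was 1.20 in B16F10, −0.011 in 4T1, 0.11 in LL2 and −0.17 in TC1. Without replicate 4 of every model 2 genes passed, without replicate 5 of every model 1 gene, and without the expression filter 10.

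Whether the muDX400 effect followed response class was tested with the 11 models as replicates. The signature effect averaged 0.22 ± 0.09 in Resistant, 0.54 ± 0.25 in Partial and 1.30 ± 0.51 in High models (SD over models, n = 4, 4 and 3), a slope of 0.53 per class step. The exact 2-sided permutation test over 11550 arrangements gave p = 0.00026 (adjusted over the 3 signature measures, 0.000779). High exceeded Resistant by 1.08 (exact p = 0.0286). The effects compare libraries of the same sample-number block, and within the blocks they were 0.09 (TC1), 0.29 (LL2), 0.52 (EMT6) and 1.88 (MC38). In the next block they were 0.22 (4T1), 0.22 (MB49), 0.83 (CT26), 1.00 (CM3) and 1.00 (MBT2), and in the last 0.28 (B16F10) and 0.60 (RENCA).

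Among the 29 lists 11 followed class. The Resistant, Partial and High means were 0.13, 0.35 and 1.11 for pan T cell (slope 0.48) and 0.10, 0.34 and 1.09 for checkpoint and exhaustion (0.48). They were 0.12, 0.36 and 1.20 for CD8 T cell and cytotoxicity (0.53) and 0.08, 0.31 and 0.74 for CD4 and regulatory T cell (0.33). Means of 0.32, 0.53 and 1.20 were found for interferon-gamma response (0.43) and 0.22, 0.41 and 1.18 for MHC class II (0.47). They were 0.10, 0.30 and 0.88 for macrophage and monocyte (0.38) and −0.01, 0.20 and 0.45 for dendritic cell (0.23). Proliferation (−0.02, −0.17 and −0.52) and erythroid genes (0.26, −0.42 and −0.79) went the other way. The adjusted exact permutation p was 0.0013 for pan T cell and checkpoint, 0.0019 for the signature and CD4, 0.0020 for dendritic cell and 0.0042 for CD8. It was 0.0172 for interferon-gamma, 0.0198 for proliferation and 0.0281 for MHC class II, macrophage and erythroid. The next lists, type I interferon and adipocyte, had an adjusted exact p of 0.0763, and the other 16 lists did not pass. Left-out models ended calls for macrophage (without 4T1, 0.39; B16F10, 0.34; CM3, 0.33; MC38, 0.27), erythroid (without B16F10, −0.53; CM3, −0.54; MC38, −0.47; TC1, −0.42) and MHC class II (without MBT2, 0.42; MC38, 0.40; TC1, 0.44). They also did for proliferation (without CM3, −0.18) and interferon-gamma response (without MC38, 0.35). Trend removal ended the erythroid call (adjusted exact p = 0.0639).

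**Figure D3:**
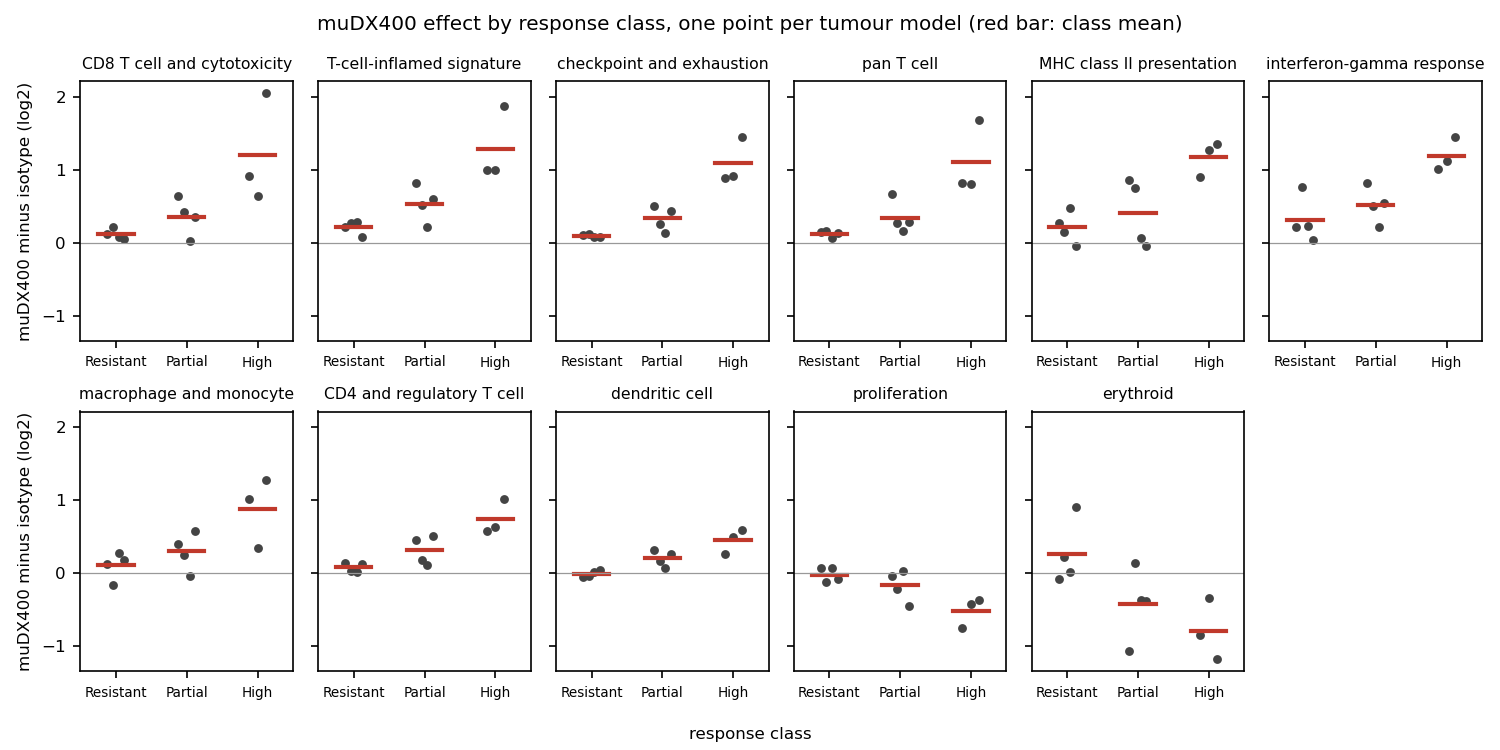
Mean muDX400 minus isotype difference in log2(FPKM + 1) over list members for the 11 lists that followed response class, with a point per tumour model and a bar at the class mean. Pan T cell genes averaged 0.13 in Resistant, 0.35 in Partial and 1.11 in High models, and proliferation genes −0.02, −0.17 and −0.52.

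Single genes did not pass the class test. The slopes of Pdcd1, Cd274 and Cd8a were 0.65 ± 0.16, 0.86 ± 0.17 and 0.73 ± 0.20 log2 units per class step (SE, n = 11 models), with adjusted p = 0.0966, 0.0966 and 0.0983 in limma. The 10 genes with the smallest p, none past the threshold, were Nos2 (0.80 ± 0.14), the inducible nitric oxide synthase, Clec9a (0.46 ± 0.09), a receptor of cross-presenting dendritic cells, and Acod1 (1.00 ± 0.19). The others were Zbtb32 (0.44 ± 0.09), Traf3ip3 (0.40 ± 0.08), Il18r1 (0.45 ± 0.09), Oas3 (0.45 ± 0.09), Mmp25 (0.52 ± 0.10), Samhd1 (0.54 ± 0.11) and the centromere gene Cenpp (−0.31 ± 0.06), all at adjusted p = 0.0966. Limma passed 0 of 16187 genes, with 3911 at an unadjusted p under 0.05. Adjusted over the list alone, the members following class were 14 of 14 in pan T cell, 13 of 14 in CD8, 15 of 18 in the signature and 11 of 13 in checkpoint. They were 8 of 10 in CD4, 16 of 24 in interferon-gamma, 10 of 10 in MHC class II, 11 of 15 in macrophage and 10 of 15, all lower, in proliferation.

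Levels before treatment were compared across classes to ask what separates the models at baseline. The signature averaged 3.19 in Resistant, 4.35 in Partial and 4.26 in High models, a slope of 0.57 (exact 2-sided permutation p = 0.0703), and High exceeded Resistant by 1.07 (exact p = 0.114). In the first sample-number block it was 3.98 (4T1), 2.93 (LL2), 4.74 (CT26), 3.21 (EMT6), 4.59 (MB49), 3.90 (CM3), 4.67 (MBT2) and 4.21 (MC38). The block with deeper baseline libraries held no High model, at 2.25 (B16F10), 3.61 (TC1) and 4.87 (RENCA), so class is partly confounded with block and depth. Pdcd1, Cd274 and Cd8a had slopes of 0.75 ± 0.34, 0.94 ± 0.34 and 0.81 ± 0.33 (SE, n = 11 models, adjusted p = 1.00 in limma). Among the genes that can be named the smallest p belonged to Fam69b (−1.21 ± 0.23), the X-linked lymphocyte genes Xlr4b (1.30 ± 0.26) and Xlr (1.91 ± 0.41), and Plk2 (1.11 ± 0.25). Next were Fdx1 (−0.50 ± 0.12), Ubtd1 (−0.64 ± 0.16), Cdr2l (0.82 ± 0.20), Cxcl9 (1.67 ± 0.41), an interferon-induced chemokine, Serpina3f (1.12 ± 0.27) and Tmem121 (−1.03 ± 0.26), all at adjusted p = 1.00. Limma passed 0 of 14009 genes (lowest adjusted p = 0.185, for a gene that counts in totals only), with 431 at an unadjusted p under 0.05 and 1 passing without CT26, and the lowest adjusted exact p over the lists was 0.424. A simulated slope of 1 was recovered for 59% of genes and a slope of 2 for 88%. These slopes were put in genes drawn at random, with independent noise. Such shares do not give the power for genes of larger spread between models, such as Xlr or Cxcl9, whose slopes of 1.91 and 1.67 did not pass.

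In isotype tumours at 8 days the signature averaged 2.86 in Resistant, 4.32 in Partial and 4.24 in High models, a slope of 0.73 (exact 2-sided permutation p = 0.0426, adjusted 0.0639), with High above Resistant by 1.38 (exact p = 0.114). Within the sample-number blocks it was 2.80 (TC1), 2.07 (LL2), 3.77 (EMT6) and 4.08 (MC38). In the next block it was 4.31 (4T1), 4.61 (MB49), 3.82 (CT26), 4.25 (CM3) and 4.39 (MBT2), with no order by class, and in the last 2.27 (B16F10) and 5.09 (RENCA). The raw exact p no longer passed without B16F10 (slope 0.59), CM3 (0.80), CT26 (0.73), EMT6 (0.73), LL2 (0.56), MB49 (0.72), MBT2 (0.77) or TC1 (0.68). Slopes were 0.87 ± 0.31 for Pdcd1, 0.88 ± 0.31 for Cd274 and 0.95 ± 0.33 for Cd8a (SE, n = 11 models, adjusted p = 0.990 in limma). Among the genes that can be named the smallest p belonged to Xlr4b (1.48 ± 0.28), Fam69b (−1.18 ± 0.23), Xlr (1.96 ± 0.40) and Ubtd1 (−0.67 ± 0.14). Next were Fgl2 (1.41 ± 0.32), Gbp8 (1.55 ± 0.36), Smim26 (0.54 ± 0.13), Eps8 (−0.92 ± 0.22), Mdp1 (0.66 ± 0.16) and Plk2 (1.11 ± 0.27), all at adjusted p = 0.990. Limma passed 0 of 13589 genes (lowest adjusted p = 0.664, for a gene that counts in totals only), with 640 at an unadjusted p under 0.05 and 1 passing without CT26. CD8 (slope 0.79, exact p = 0.0327), pan T cell (0.59, 0.0357), checkpoint (0.49, 0.0442) and interferon-gamma (0.94, 0.0461) had the smallest exact p among the lists. None passed the adjustment (lowest adjusted exact p = 0.225).

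The last comparison, isotype tumours at 8 days against baseline over the 11 models, addressed what changed with time on control antibody. Erythroid genes rose in 5 of 5 (mean 1.03; Hba-a1 1.30 ± 0.23; Hbb-bs 1.21 ± 0.24) and neutrophil genes in 8 of 13 (mean 0.28; Retnlg 0.70 ± 0.11). Early stress genes rose in 8 of 10 (9 adjusted over the list alone, mean 0.31; Egr1 0.44 ± 0.07; Fos 0.42 ± 0.08) and hypoxia and glycolysis genes in 7 of 12 (8, mean 0.22; Slc2a1 0.40 ± 0.08). Type I interferon response genes fell in 15 of 16 (16, mean −0.35; Isg15 −0.60 ± 0.09; Mx2 −0.38 ± 0.07). These list directions kept their sign under each scaling. In RENCA and B16F10 alone, whose arms share a sample-number block, the means were 0.41 for erythroid (0 of 5 past the threshold), 0.21 for neutrophil (1 of 9), 0.22 for early stress (4 of 10), 0.14 for hypoxia (1 of 12) and −0.31 for type I interferon (0 of 16). The arms of these models still differed in depth. Baseline libraries had 39.8 to 44.7 M fragments in RENCA and 36.7 to 50.4 M in B16F10, and isotype libraries 16.7 to 19.4 M and 19.9 to 22.2 M. The erythroid mean was lower at 8 days in RENCA (5.16 at baseline, 4.84 in isotype), CM3 and TC1. The neutrophil mean was lower in TC1 (1.92 and 1.11), MBT2 and MB49, the hypoxia mean in MBT2 (5.53 and 5.29), MB49, CT26 and EMT6, and the early stress mean in MBT2 (4.574 and 4.569). The type I interferon mean was higher at 8 days in EMT6 (4.39 and 4.80), CM3 and MB49, and fell most in CT26 (5.68 and 4.28) and TC1 (5.48 and 4.13). Pdcd1 (0.11 ± 0.10, adjusted p = 0.462), Cd274 (−0.09 ± 0.13, 0.654) and Cd8a (0.15 ± 0.12, 0.373) did not pass.

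The largest falls belonged to short transcripts and pseudogenes, whose reads may be shared with their parent genes: Llph-ps2 (−3.53 ± 0.13), the small RNA gene Bc1 (−2.93 ± 0.19), mt-Atp8 (−2.84 ± 0.10) and Trmt112-ps2 (−2.73 ± 0.13). Next were Tpt1-ps3 (−1.73 ± 0.08), Ptges3-ps (−1.65 ± 0.12), Pdcd5-ps (−1.64 ± 0.13), Ndufc1 (−1.60 ± 0.09), Atp5k (−1.35 ± 0.11) and Tmsb10 (−1.33 ± 0.11). The largest rises were Ftl1-ps1 (1.28 ± 0.06), Kansl2-ps (1.01 ± 0.09), Hist2h2aa1 (0.87 ± 0.15), Gemin4 (0.68 ± 0.07) and Alas2 (0.62 ± 0.15), the erythroid haem enzyme. Next were Tnfrsf9 (0.55 ± 0.07), a costimulatory receptor of activated T cells, Cd14 (0.53 ± 0.07), Ier3 (0.51 ± 0.10), Junb (0.50 ± 0.05) and Cebpd (0.48 ± 0.05). Limma passed 4766 of 16305 genes, 672 higher and 4094 lower. The split was 1403 and 2563 after median-ratio scaling, 2963 and 1867 after quantile normalisation, and 3358 and 2126 after removal of GC and length trends. Which direction held more genes depended on the scaling. Baseline and 8-day libraries fell in different sample-number blocks for 9 models. In RENCA and B16F10, whose arms share a block but differ in depth, 1130 of 13460 genes passed, 206 higher and 924 lower. All 10 falls named here passed in these models alone, as did Ftl1-ps1, Kansl2-ps, Gemin4, Junb, Cebpd and Tnfrsf9, while Alas2 (0.56), Cd14 (0.66), Hist2h2aa1 (0.48) and Ier3 (0.23) did not.

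Members of the remaining lists mostly fell or did not pass with time, with the number adjusted over the list alone given where it differs. Over all genes 4094 of 16305 were lower. Many of the counts below, among them those of the signature, pan T cell, interferon-gamma and proliferation lists, lay near or under that share. Members fell in 6 of 24 for interferon-gamma response (Gbp3 −0.54 ± 0.13), 3 of 18 for the signature, 3 of 14 for pan T cell, 4 of 14 for CD8 (Klrd1 −0.59 ± 0.10) and 4 of 8 for CD4 (5). The counts were 4 of 9 for NK cell (Xcl1 −0.60 ± 0.11), 3 of 12 for dendritic cell, 4 of 15 for macrophage (Ly6c2 −0.74 ± 0.15), 2 of 12 for MHC class I and 3 of 13 for fibroblast and matrix (Col1a1 −0.50 ± 0.14). They also fell in 1 of 11 for endothelium, 3 of 15 for proliferation, 3 of 7 for Wnt/beta-catenin and 5 of 9 for melanocyte (Dct −0.33 ± 0.06). Outside B16F10 and CM3 the Dct medians were near the floor, at 0.426 FPKM in first-block baseline libraries and 0 to 0.0625 FPKM at 8 days. Dct did not fall in RENCA and B16F10 alone. Counts were 4 of 9 for epithelial (7), 2 of 4 for keratinocyte (3; Krt14 −0.60 ± 0.09), 2 of 10 for muscle and 2 of 9 for mitochondrial transcripts (mt-Atp6 −0.42 ± 0.09). Checkpoint had 1 higher and 1 lower of 13, TGF-beta 1 higher and 2 lower of 11 (1 and 3), and MHC class II, B cell, adipocyte and mast cell 0 past the threshold. Under at least 1 of the other scalings the list mean changed sign for checkpoint, endothelium, mast cell, dendritic cell, macrophage, Wnt, CD8 and mitochondrial genes. In RENCA and B16F10 alone the means of the signature, pan T cell, CD8, checkpoint, MHC class I and II, B cell and mast cell lists were above 0.

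**Figure D4:**
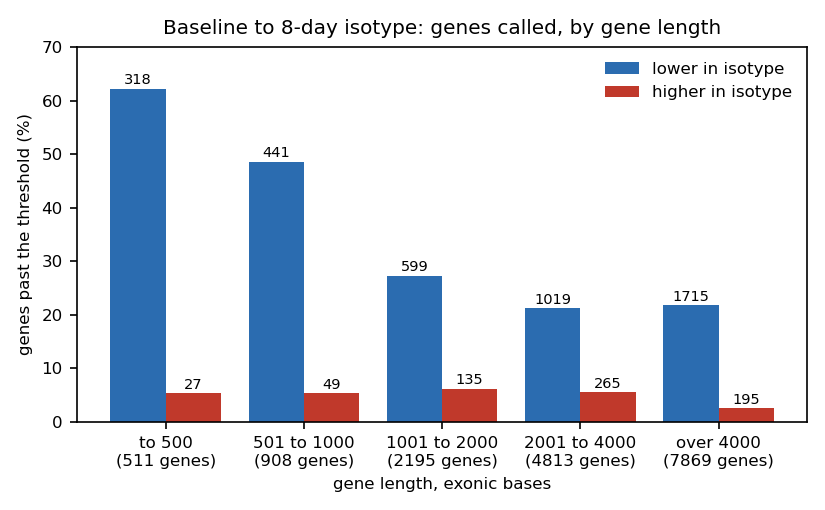
Percent of tested genes lower (blue) or higher (red) in 8-day isotype than in baseline tumours over 11 models, by the number of exonic bases of the gene, with the number of genes over each bar. Of 511 genes of up to 500 bases 318 were lower, and of 7869 genes over 4000 bases 1715 were lower, with the balance of directions turning to higher after quantile normalisation.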

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

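All tests of explanations in this part, and the counts over other splits of the samples, were chosen after the result was seen, except the test of GC content for the CM3 isotype libraries; the slopes with response class were planned.

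For Pdcd1, Cd274, Cd8a and the signature, 6 of 88 combinations of measure and group of 5 tumours held a library far from the others. Chance gives about 1 in 20 such combinations, and the 4 measures share the same tumours. Pdcd1 in LL2 isotype replicate 2 was 0.344 on the log2(FPKM + 1) scale beside 0.0605 to 0.0940 in the others. Pdcd1 in TC1 isotype replicate 4 was 0.274 beside 0.667 to 0.800. Cd274 in CT26 isotype replicate 2 was 4.03 beside 3.28 to 3.41. Cd274 in RENCA was 3.85 in isotype replicate 1 beside 4.37 to 4.54, and 4.62 in muDX400 replicate 5 beside 5.46 to 5.79. Cd8a in MC38 muDX400 replicate 5 was 3.49 beside 4.81 to 5.33.

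The muDX400 effect differed between response classes, by the permutation test over models, for 11 lists. The slopes in log2 units per class step were 0.53 for the T-cell-inflamed signature, 0.48 for pan T cell, 0.53 for CD8 T cell and cytotoxicity, 0.33 for CD4 and regulatory T cell and 0.48 for checkpoint and exhaustion. They were 0.43 for interferon-gamma response, 0.47 for MHC class II presentation, 0.23 for dendritic cell, 0.38 for macrophage and monocyte, −0.24 for proliferation and −0.53 for erythroid genes. Many of these lists share genes or cells, so they are not independent results.

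CM3 isotype replicates 2 and 3 stood apart from the other CM3 libraries, with which they correlated at 0.84 to 0.90 and 0.77 to 0.86. Among the others the median was 0.956 and the lowest 0.815, so by this measure replicate 2 lay within their spread. Both replicates correlated best with the mean of the other CM3 libraries (0.913 and 0.868, next B16F10 at 0.785 and 0.770). So 0 of the 2 was closer to another model, which argues against a wrong label from another model. The slope of the deviation of replicate 3 on GC content, 0.0864 per 10% GC, lay inside the range of −0.722 to 0.974 over 100 other 8-day libraries, and its depth of 14.8 M fragments was not the lowest, so neither GC content nor depth accounts for it. Its slope on gene length was −0.307 per doubling, outside the −0.204 to 0.106 of those libraries, so a loss of long transcripts in these libraries is a candidate explanation, tried after GC content had failed. Of 3901 genes at or above 3 log2 units in the other 141 libraries, 9 and 41 were under 2 in these libraries, and no biological explanation was tested. Without these replicates the signature difference of CM3 was 0.70 (exact 2-sided permutation p = 0.107), and without replicate 4 as well 1.16 (0.0476). Replicate 4, with the highest isotype score, was left out after the data were seen, and 0.0476 is the smallest p that 21 arrangements allow.

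The CD8 T cell and cytotoxicity list passed in limma's fry as higher under muDX400 in MC38, MBT2 and CM3, though no single gene passed in MBT2 or CM3. No call was kept in camera with an estimated correlation, which passed 0 pairs of model and list in any model. The CM3 call held in 1 of 10 fits with a library left out. A lower share of tumour cells in the sample would raise markers of every other cell type alike. The list rose by 0.784 log2 units more than the macrophage and monocyte list in MC38 (exact 2-sided permutation p = 0.00794, the smallest it can give) and by 0.301 more in MBT2 (0.0159), which argues against a lower tumour share as the whole cause there. In CM3 the difference was −0.0992 (0.484) and the explanations cannot be told apart. The comparison list was changed from fibroblast to macrophage after contrasts with 5 lists had been seen, because tumour cells may express collagens; in MC38 the other contrasts were 1.14 to 2.02. In MBT2 they were 0.552 against fibroblast (exact p = 0.0476), 0.615 against endothelium (0.0397), 0.255 against neutrophil (0.143) and 0.506 against B cell (0.00794), and in CM3 −0.0526 (0.873), 0.315 (0.0476), 0.388 (0.0238) and 0.619 (0.0238). A change in T-cell number and a change in expression per cell both stay open and were not tested.

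More genes were lower than higher from baseline to isotype, most of all short ones. The median gene of up to 500 bases was lower in 11 of 11 models (−0.37 to −0.14), and 62.2% of such genes were lower against 21.6% of those over 2000 bases, so a weaker recovery of short transcripts in the 8-day libraries may account for the short genes. In the 8 models whose baseline libraries were not deeper, 3000 of 3812 passing genes were lower, which argues against depth. After quantile normalisation 1867 genes were lower against 2963 higher, so the direction of the imbalance depended on the scaling and the scale of the deposited values is not excluded. Time on study and the sample-number block stay confounded in 9 of the 11 models, and time and depth in RENCA and B16F10. The biological change with time stays open.

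Other splits of the same samples show how often a count as large as the real one arose. The shares were not adjusted over the results that were split. Of 100 splits each, real one included, a count as large came from 1 for MC38 (3482 genes, highest other 1448) and 1 for TC1 (10, highest other 8). It came from 2 for RENCA (325, highest other 615) and 3 for CT26 (41, highest other 2909). It came from 1 for the High mean (6810, highest other 4937), 2 for the Partial mean (1078, highest other 1985) and 1 for baseline to isotype (4766, highest other 70). Each of these shares was under 0.05 before any adjustment. The real count was the highest for MC38, TC1, the High mean and baseline to isotype, in TC1 by 10 against 8. In RENCA, CT26 and the Partial mean another split passed more genes than the real one, so chance is not excluded there. For the muDX400 effect by class 2 of 100 arrangements gave as many genes at an unadjusted p under 0.05 as the real 3911 (highest other 4311). That share is also unadjusted, and 0 genes passed the adjusted threshold, so chance is not excluded there either. For baseline levels 71 did (431, highest other 1971) and for isotype levels 44 (640, highest other 2198), so chance was not excluded for these levels. Results of 0 genes are met by all 100 splits whatever the data, so that share carries no information. The highest other count was 628 in 4T1, 12 in B16F10, 1 in CM3, 1126 in EMT6, 881 in LL2, 1 in MB49 and 925 in MBT2. It was 22 for the Resistant mean, 404 for the effect by class, 1 for baseline and 11 for isotype levels. Splits that passed many more genes than the real one, as in CT26, 4T1, EMT6, LL2 and MBT2, point to a structure of the samples, whose source was not tested.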

How the results depend on the processing

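The alternatives that left out CM3 or RENCA isotype libraries, tested lists without each library, followed list means over scalings and models, used only the 8 models of the first baseline block or removed GC and length trends were chosen after seeing the data; the others were planned. Of 689 alternatives of main results 587 kept their side of the threshold or, for counts, a total within 1.5 times. Counts were compared by their total only, so a turn between higher and lower was not scored. Such turns, given above, came after quantile normalisation and trend removal in the High mean and with time, and after trend removal in MC38. No signature difference or slope changed sign. The causes of the changes below were not tested, except that leaving out libraries leaves fewer samples. A spread shared over all 8-day libraries passed 2 genes in 4T1, 70 in B16F10, 6662 in CM3, 8 in EMT6, 6 in LL2, 71 in MB49, 241 in MBT2, 2629 in RENCA and 4 in TC1. Without the filter the counts were 1 in CM3, EMT6, LL2, MBT2 and TC1, 21 in CT26, 127 in RENCA and 10 for the Resistant mean. Quantile normalisation gave 2 in CM3, 146 in CT26 and 6 in TC1, and median-ratio scaling 94 in CT26 and signature differences of 0.85 in CT26 and 1.94 in MC38 (adjusted exact p = 0.0437). A minimum change of 1 log2 unit left 5 genes in CT26, 731 in MC38, 204 in RENCA and 3 in TC1. With the mouse as replicate 4517 genes followed class in their effect, but class is a property of the model, so this count covers these models only. High against Resistant only gave 1 gene for baseline and 1 for isotype levels, and model as a correlated block 12 and 50. RENCA and B16F10 alone passed 1130 genes with time. Z-scores gave an isotype slope of the signature of 0.49. Camera passed 138 pairs of model and list with a preset and 0 with an estimated correlation. Without CM3 isotype replicates 2, 3 and 4, CM3 passed 4854 genes and the isotype slope was 0.70, which no longer passed; removal of GC and length trends gave 816 genes in MBT2 and 604 in RENCA.

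The replicate numbers do not pair the samples: no model had all 5 same-numbered pairs correlating over 0.1 (at most 3 did), and 0 to 2 of 5 isotype libraries per model correlated best with their own number. With the replicate block 0 genes passed in CT26, 1 in MB49, 168 in RENCA, 16 in TC1 and 3186 in MC38, and 12 pairs of model and list, while the signature could reach no exact p below 0.0625 with 32 arrangements.

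Leaving out a library gave ranges of 0 to 3942 genes in CM3, 4 to 125 in CT26, 0 to 101 in LL2 and 0 to 2595 in MBT2. They were 1769 to 4159 in MC38, 95 to 758 in RENCA, 0 to 36 in TC1 and 0 to 0 in 4T1, B16F10, EMT6 and MB49. Leaving out a replicate or model gave 0 to 2 for the Resistant, 31 to 1243 for the Partial and 4457 to 7356 for the High mean, 0 to 0 for the effect by class, 0 to 1 for baseline and isotype levels, 3820 to 5295 with time, and 7 to 11 lists following class. Calls of model and list pairs ranged from 32 to 62. Signature differences ranged over 0.17 to 0.30 in 4T1, 0.06 to 0.59 in B16F10, 0.82 to 1.31 in CM3, 0.64 to 0.95 in CT26 and 0.26 to 0.80 in EMT6. They ranged over 0.19 to 0.37 in LL2, 0.17 to 0.31 in MB49, 0.89 to 1.21 in MBT2, 1.77 to 2.05 in MC38, 0.40 to 0.71 in RENCA and 0.01 to 0.13 in TC1. Slopes with class ranged over 0.38 to 0.70 (baseline), 0.56 to 0.93 (isotype) and 0.38 to 0.57 (effect).

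Of 4631 values of named genes under other settings 4259 were unchanged in call, 274 were lost, 84 gained and 14 reversed, and of 7373 with a library or model left out 6615, 563, 193 and 2. The reversals were, in the High mean, Egln3 (−0.0079, range to 0.72) and Tyrp1 (0.00, range to 0.42) without CM3, and Tyrp1 (−0.0016) and Slc45a2 (−0.082) without CM3 isotype replicates 2, 3 and 4. With time in RENCA and B16F10 only they were Psmb10 (0.23), Cd5 (0.058), Cd2 (0.075), Ctsw (0.20), Cxcl10 (0.055), Ncr1 (0.074), Fscn1 (0.29), Fcgr1 (0.023), Dct (0.029), Pmel (0.18), Tyrp1 (0.041) and Slc45a2 (0.029). Pdcd1 and Cd8a were below the expression filter in B16F10, LL2 and TC1 and were not tested there.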

Other observations

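The fit without RENCA isotype replicate 2 was chosen after the result was seen, and the other values come from no test. Melanocyte transcripts were seen at a low level in models of other tissues. In the 21 baseline libraries of the first sample-number block that are not CM3, Tyrp1, a melanin enzyme, had a median of 0.375 FPKM (0.141 to 2.27) and Dct, another, 0.426 FPKM (0.189 to 2.12). In the 8-day libraries of TC1, EMT6, LL2 and MC38 the Tyrp1 median was 0 FPKM (0 to 0.158), and in those of MBT2, MB49, CT26 and 4T1 it was also 0 FPKM (0 to 1.25). The CM3 baseline libraries of the same first block had medians of 2015 FPKM for Tyrp1 and 3358 for Dct. In the block shared with B16F10, the Tyrp1 median was 0.129 FPKM (0 to 0.348) in the 8-day RENCA libraries and 0.107 FPKM (0.0455 to 0.151) in the baseline libraries of RENCA and TC1. B16F10 8-day libraries ranged from 2084 to 3474 FPKM of Tyrp1.

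Single tumours had high scores for lists of other cell types. RENCA isotype replicate 2 had a B and plasma cell list score of 5.94, and CM3 isotype replicate 4 a skeletal muscle score of 6.92. The mitochondrial share of FPKM was highest in B16F10 muDX400 replicate 1, at 14.1%. Leaving out RENCA isotype replicate 2 gave 1270 genes for the Partial mean against 1078 with it.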
